A study of Mus musculus with 9 samples.

How the data were processed

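OPCs derived from the mouse epiblast stem cell lines 129O1 and EpiSC5, and O1-positive OLs were harvested on a magnetic cell sorter, crosslinked and used for ChIP with 9 µg per sample of an H3K27ac antibody or 15 µg per sample of a SOX6 antibody, per the labels' protocols. The labels describe 9 samples. Peak lists of 7 of them were used here, and the 2 input samples, titled as embryonic stem cells but described as OPCs elsewhere in their labels, were not analysed here. Per the submitters' processing notes the tools were Trim Galore 0.3.1, Bowtie2 2.3.2, Picard, deepTools and bedtools and the genome build was mm10. The peak caller, its version and the control used for calling are not given in the sources used here. Each list belongs to 1 library, so peaks were called or at least listed per library and not on pooled replicates. Between 6 and 37 numbers of each list's running peak names were absent.

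The deposited lists have no header. H3K27ac lists have 9 columns in the broad-peak layout and SOX6 lists have 10 in the narrow-peak layout, which also gives a summit. The deposited score of each peak was 10 times its −log10 q, truncated to a whole number, within 1 for 2 peaks of each H3K27ac list and exactly for all other peaks. The authors' fold enrichment, a ratio of signal over background per peak, and their −log10 p and −log10 q were used only to describe, rank or filter peaks within a list. The lowest −log10 q in each list was just above 3, and the median was 17.6 and 12.8 in OPC H3K27ac of 129O1 and EpiSC5, 10.8 and 9.48 in OL H3K27ac, 19.2 and 19.9 in OPC SOX6 and 10.6 in OL SOX6. The protocols name 2 sequencers with different read lengths without saying which library ran on which, so that batch could not be examined. They state a minimum number of reads per sample, but the lists hold no counts, so depth per library is unknown and no counting interval can be given. Lists from a deeper or cleaner library are longer, which bears on every comparison of presence and absence.

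Peaks on chromosomes 1 to 19, X and Y were used. Gene positions came from an NCBI RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 names, and all members of the fixed gene lists were found in it. It gives no strand and no exons, so promoters, introns and start sites were not analysed. No genome sequence was used, so the planned SOX motif test was not run. Coordinates are 1-based.

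Lists were compared by overlap of at least 1 bp. H3K27ac peaks of the 4 lists were merged into regions and classed by presence. For each protein-coding gene the H3K27ac-covered length within the body plus 10 kb each side was scaled to equal total covered length per list and taken as log2 of covered kb plus 1. Changes are on that scale and understate those of genes with little coverage. Genes with a mean of at least 1 kb were tested with limma (trend, cell line and state as terms, 1 residual degree of freedom, prior 5.04), with Benjamini-Hochberg adjustment. A gene was called at adjusted p under 0.05 with the same sign in both lines. The cell line entered the main model because OPC and OL of a line come from the same cell line, and their replicate numbers follow it. As a check, 11 genes differed between the lines at adjusted p under 0.05 (limma). The 2 lines were the replicates, so p-values measure only the spread between these samples. In simulated data for this comparison with 12459 genes and the spread of the real lists, limma called 32.0% of 50 genes changed by log2 1, 82.0% at 1.5, 98.0% at 2, 98.0% at 3 and 16 of 12259 unchanged genes. Far fewer genes were changed there than were called in the real lists, and simulated values had no lower limit, unlike covered lengths. These rates therefore need not hold for the real comparison.

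The 13 gene lists were fixed before the data were examined and cover OPC, immature oligodendrocyte, myelin, lineage transcription factor, MAPK feedback, cholesterol, cell cycle, astrocyte, neuron, microglia, pluripotency, Schwann cell and housekeeping genes. The mean change of each was set against 10000 random lists matched on deciles of covered length and gene length, two-sided, adjusted over the 13 lists, where 0.0002 is the smallest raw p. SOX6 shares were set against 1000 circular shifts of the list within each chromosome, one-sided. Broad domains were H3K27ac peaks joined within 12.5 kb and split where the scaled rank curve has slope 1. Genes are named by a rule fixed in advance, which takes the 10 largest calls in each direction, up to 10 called members of the first 3 lists, 11 genes always given, and the 10 genes with most SOX6 in OPC and in OL. Some of the genes it takes are not reported here. Others named were members of the fixed lists or were singled out after their values were seen, as were Fyn and Tns3 beside SOX6.

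The alternatives tried were another pseudocount, filter, scaling, window, overlap rule, random placement, stitching distance and domain ranking, shorter lists by score, a model without the cell line, and each line alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.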

Results

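Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 targets in mouse oligodendrocyte progenitor cells (OPCs) and in O1-positive oligodendrocytes (OLs) made from them. OPCs are the dividing precursors of the cells that make myelin. H3K27ac is an acetylated histone residue found at active promoters and enhancers, and SOX6 is a transcription factor of the oligodendrocyte lineage. The series title links gene melting to the timing of oligodendrocyte maturation, and the comparisons below ask how acetylation and SOX6 occupancy differ between the 2 states. Both cell types came from 2 epiblast stem cell lines, 129O1 and EpiSC5, which served as the 2 replicates. H3K27ac was mapped in OPC and OL of both lines, giving 4 peak lists. SOX6 was mapped in OPC of both lines and in OL of EpiSC5 alone, giving 3 lists, so the SOX6 comparison of OPC with OL had no replicate in OL. The H3K27ac lists held 30846 peaks in OPC of 129O1, 27731 in OPC of EpiSC5, 33808 in OL of 129O1 and 31060 in OL of EpiSC5, covering 48.7, 37.2, 50.9 and 43.5 Mb. The SOX6 lists held 22883 peaks in OPC of 129O1, 15490 in OPC of EpiSC5 and 3949 in OL of EpiSC5, covering 8.11, 5.37 and 1.18 Mb. Peak lists carry no read counts, so the depth of each library is unknown here.

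The first comparison asked which H3K27ac regions were held by OPC or by OL. Of 49676 merged regions, 14965 were present in all 4 lists. OPC lists of both lines, and no OL list, held 5490 regions. OL lists of both lines, and no OPC list, held 8301 regions. Patterns that followed the cell line in place of the state were rarer, with 1193 regions in both 129O1 lists alone and 224 in both EpiSC5 lists alone. The crossed pairs of lists held 120 and 88. Many regions lay in a single list, 3751 and 1811 in OPC of 129O1 and EpiSC5 and 3509 and 4656 in OL. Others were missing from 1 list alone, 523 and 1086 from OPC of 129O1 and EpiSC5 and 438 and 3521 from OL. Lists thus also differed often without a pattern by state or line. With 2 lines per state an exact test of 2 against 2 cannot go below p = 0.33, so these counts carry no test beyond the repeat in the second line. Called from a single line the counts were between 9814 and 11201 OPC regions and between 12608 and 14547 OL regions, and from the higher-scoring 50% of each list they were 2476 and 4045, of which 27.02% and 59.2% were absent from the full lists of the other state. With equal numbers of peaks taken by score they were 6032 and 6459, so most of the excess of OL over OPC regions went with the length of the lists.

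**Figure D1:**
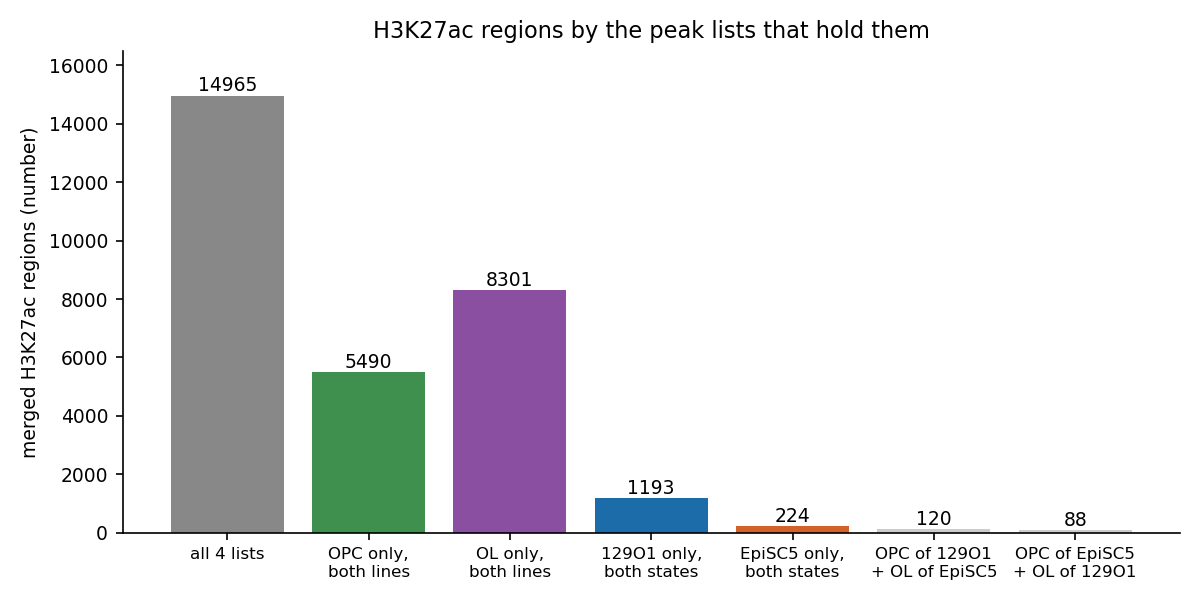
Number of merged H3K27ac regions (vertical axis) by the peak lists that hold them, for 4 libraries, 1 per state and line. Regions held by 1 list or by 3 lists are not drawn. Regions repeated across lines by state, 5490 for OPC and 8301 for OL (6032 and 6459 with equal numbers of peaks), outnumber those that follow the line, 1193 and 224, or a crossed pair, 120 and 88.

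The widest region held by OPC alone spanned 6391 bp on chromosome 18 from 38902747 to 38909137 (mm10) and overlapped Fgf1, which encodes an acidic fibroblast growth factor, and Arhgap26. The widest held by OL alone spanned 19834 bp on chromosome 8 from 111607237 to 111627070, over Znrf1 and Ldhd. The next, 19076 bp on chromosome 2 from 29840086 to 29859161, covered Cercam, Urm1 and the microRNA genes Mir219a-2 and Mir219b. Fyn, a Src-family kinase active in oligodendrocyte differentiation, and Tfeb, a regulator of lysosomal genes, held OL regions of 13627 and 12338 bp. Of the 5 widest regions present in all 4 lists, 3 contained Mir9 genes, led by 41421 bp at Mir9-3 on chromosome 7 from 79496237 to 79537657. The width is that of the merged peaks, and an overlap of 1 bp counts as presence. At Mir9-3 the width came mostly from 129O1. From 79497731 to 79536452, peaks covered 38.7 kb in OPC and 35.0 kb in OL of 129O1. In EpiSC5 they covered 14.8 and 13.7 kb.

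The second comparison asked which genes gained or lost H3K27ac breadth, the length of the gene body plus 10 kb each side that peaks cover. Breadth grew in OL at Lhfpl2 by 3.72 ± 0.23 on the log2 scale (limma SE, n = 2 lines), at Fyb by 3.58 ± 0.22 and at Enpp6, a choline phosphodiesterase that marks newly formed oligodendrocytes, by 3.52 ± 0.17. Enpp6 (chromosome 8, 46939197 to 47096762) had 0 and 0.411 kb in OPC of 129O1 and EpiSC5, against 12 and 15.4 kb in OL. The 10 largest gains also included Ldhd (3.49), Plcg2, a phospholipase (3.45), Prima1, a membrane anchor of acetylcholinesterase (3.28), Nfasc, an adhesion molecule of axon–glia contacts (3.27), Fgf7 (3.07) and Tnr, the matrix protein tenascin R (3.0). Tnr reached the largest breadth of these, 153 and 114 kb in OL against 17.7 and 11.2 kb in OPC.

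Breadth shrank most at Chrm3, the muscarinic receptor M3, by −3.88 ± 0.24 (SE, n = 2 lines), from 20.3 and 8.25 kb in OPC to 0 kb in OL of both lines. Fgf1 followed at −3.07 ± 0.18 and Stat6, a cytokine-activated transcription factor, at −3.0 ± 0.18. Ccnd1, which encodes cyclin D1 (chromosome 7, 144929931 to 144939831), fell by 2.88 ± 0.19, from 8.37 and 6.17 kb to 0.412 and 0 kb. Plxdc2 (−2.90), Dpyd (−2.88), Mest (−2.83), Lancl3 (−2.71), Spry4, a feedback inhibitor of receptor tyrosine kinases (−2.68), and Mmp15, a membrane-bound metalloproteinase (−2.66), completed the 10 largest losses. All 20 genes had adjusted p between 0.00195 and 0.00362 in limma. All 20 stayed under 0.05 with equal numbers of peaks, without scaling, with a pseudocount of 0.25 kb and with 50 kb each side. From the higher-scoring 50% of each list the losses held less well than the gains. There Chrm3 (−2.46), Fgf1 (−1.48), Stat6 (−2.32), Plxdc2 (−2.51), Dpyd (−2.17) and Spry4 (−2.44) were not called. Mest and Lancl3 had too little coverage to be tested, and Ccnd1 (−3.11) and Mmp15 (−3.01) fell by more than Chrm3. The 10 largest gains kept their call, but narrowly, at adjusted p from 0.0469 to 0.0470 (limma). Stat6 and Dpyd missed it narrowly, at 0.0502 and 0.0513 (limma). With 50 kb each side Stat6 stood at −1.53, Mmp15 at −1.49, Plcg2 at 1.95 and Fyb at 2.33, still called. Over the gene body alone, an alternative added after the data were seen, Mmp15 stood at −1.54. Across 12459 protein-coding genes, 1562 were wider and 2041 narrower in OL at adjusted p under 0.05 with the same sign in both lines, and 5541 had an unadjusted p under 0.05. A change of at least 1 on the log2 scale was shared by both lines for 636 wider and 468 narrower genes, and 3 genes changed by that much in opposite directions.

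The changes of the 2 lines correlated across genes (Pearson r = 0.815, genes not being independent replicates), and 84.5% of genes had the same sign in both. The median gene changed by −0.24, so single changes are to be read against that value, and without scaling to equal covered length the median was −0.13. The split of calls depended on that scaling, with 43.4% of calls wider after scaling and 57.7% without it (1562 wider, 1143 narrower). From the higher-scoring 50% of each list 129 genes were wider and 43 narrower, and 27 of the named genes lost their call. Of those, Chrm3, Fgf1 and Cnksr3 (1.40 to 0.41) shrank by over 1.5 times, while others changed as much or more, such as Mobp (2.99, adjusted p = 0.0526, limma) and Ptprz1 (−2.88, adjusted p = 0.0838, limma). With no filter on covered length limma called 0 genes wider and 0 narrower, with 4814 at an unadjusted p under 0.05.

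**Figure D2:**
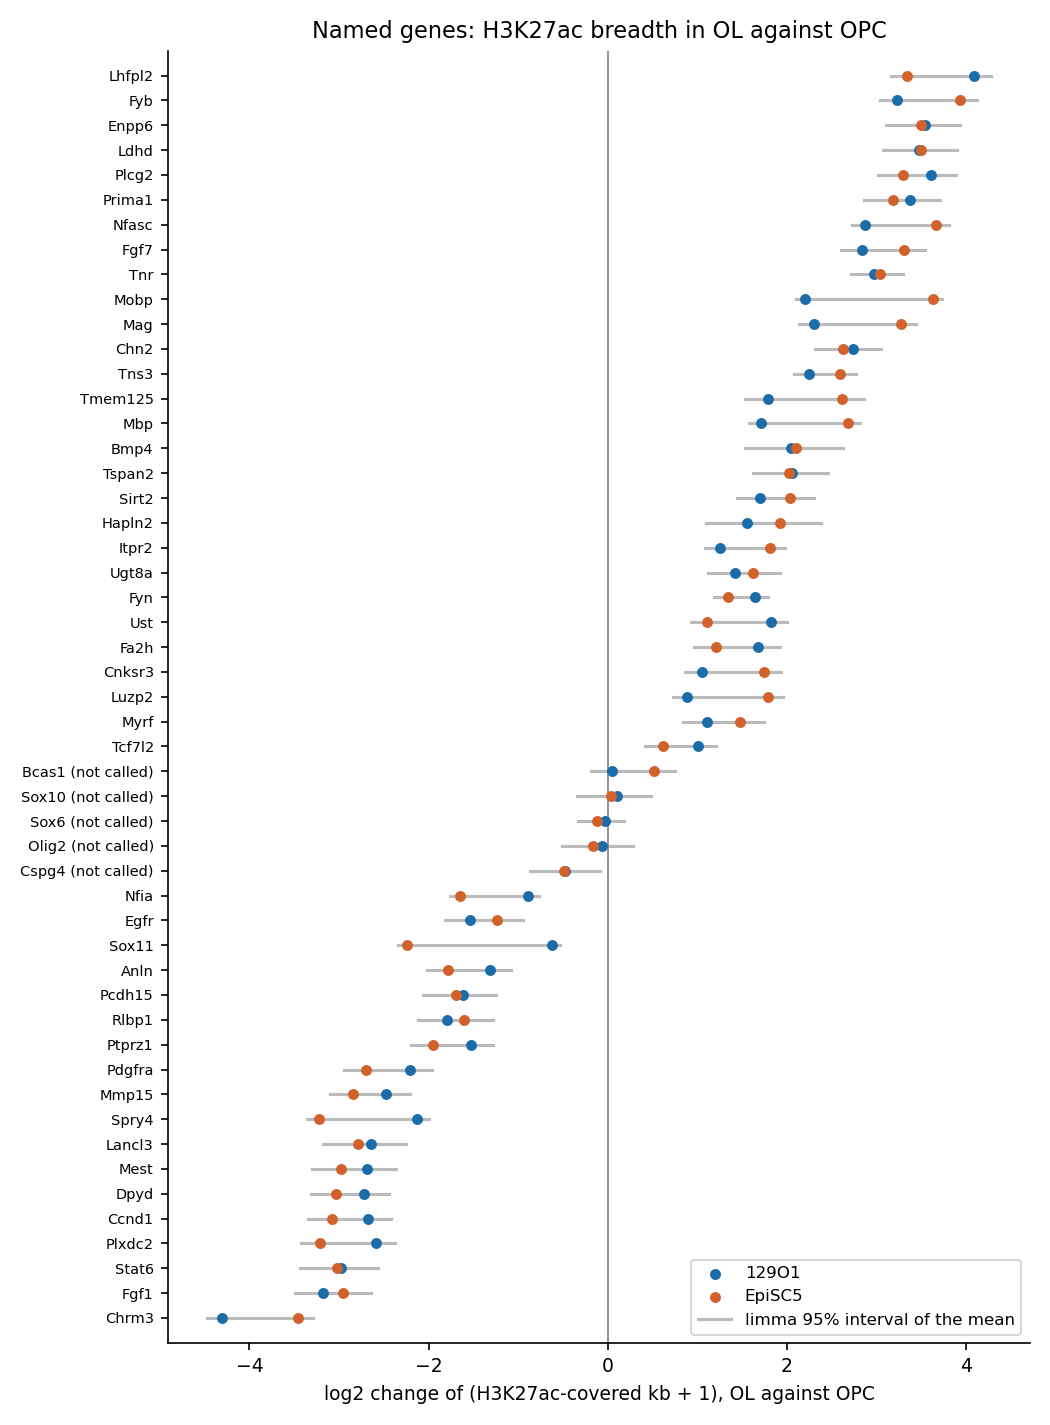
Log2 change of H3K27ac breadth (covered kb plus 1) in OL against OPC for genes taken by the naming rule, with 1 point per cell line and the limma 95% interval of their mean. Chrm3 at −3.88 and Lhfpl2 at 3.72 mark the ends, and Sox6, Sox10, Olig2, Bcas1 and Cspg4 were not called.

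Among gene groups fixed in advance, progenitor genes lost breadth. Of 29 OPC genes tested, 13 were narrower, 2 wider and 14 not called (15 narrower and 3 wider when adjusted over the list alone). The mean change lay 0.58 below that of matched random lists, a difference of −0.58 (adjusted p = 0.00052, matched random lists, lower in 2 of 2 lines). Pdgfra, the receptor for platelet-derived growth factor that defines OPCs (chromosome 5, 75151322 to 75198206), fell by 2.45 ± 0.20, from 15.2 and 13.1 kb to 2.55 and 1.54 kb. Ptprz1, a receptor phosphatase, changed by −1.74 ± 0.19, Rlbp1 by −1.70 ± 0.17, Pcdh15 by −1.65 ± 0.17, and the transcription factors Sox11 and Nfia by −1.43 ± 0.37 and −1.27 ± 0.20. Egfr, the epidermal growth factor receptor, changed by −1.38 ± 0.18, and by −2.10 with 50 kb each side. The 2 members that widened were Tnr and Luzp2, the latter by 1.34 ± 0.25 (0.89 in 129O1 and 1.79 in EpiSC5). Without the cell line in the model Luzp2 lost its call with the same change (adjusted p = 0.107, limma). From the higher-scoring 50% of each list it stood at 0.93 and was not called. Cspg4, the NG2 proteoglycan used to sort these OPCs, stood at −0.48 ± 0.16 (adjusted p = 0.0707, limma) and was not called, but was called when only genes with a mean of at least 3 kb were tested, and over the gene body alone, an alternative added after the data were seen (−0.76). Sox11 changed by −0.62 in 129O1 and −2.24 in EpiSC5, and was not called without the cell line in the model, without scaling, with a pseudocount of 0.25 kb, from equal numbers of peaks or from the higher-scoring 50% of each list.

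Genes of the next stages moved the other way. Of 25 immature oligodendrocyte genes, 14 were wider, 0 narrower and 11 not called (15 wider adjusted over the list alone), 1.05 above matched lists (adjusted p = 0.00052, matched random lists, higher in 2 of 2 lines). Besides Enpp6 and Nfasc these included Chn2, a Rac GTPase-activating protein (2.68 ± 0.15), Tns3, a tensin (2.42 ± 0.14), Bmp4, a secreted morphogen (2.08 ± 0.22), Sirt2, a deacetylase (1.87 ± 0.18), Itpr2, an inositol trisphosphate receptor (1.53 ± 0.18), Fyn (1.49 ± 0.12), Ust (1.47 ± 0.22) and Cnksr3 (1.40 ± 0.22). Tcf7l2, a Wnt effector of oligodendrocyte differentiation, rose by 0.81 ± 0.16. Bcas1, a marker of newly myelinating cells, stood at 0.28 ± 0.19 and was not called (adjusted p = 0.284, limma). Of the 32 myelin genes 25 were tested. Of these, 15 were wider, 1 narrower and 9 not called (15 wider and 2 narrower adjusted over the list alone). The list lay 0.99 above matched lists (adjusted p = 0.00052, matched random lists, higher in 2 of 2 lines). The myelin structural genes Mobp, Mag and Mbp rose by 2.92 ± 0.33, 2.79 ± 0.27 and 2.20 ± 0.25. Tmem125 (2.20 ± 0.27), Tspan2 (2.04 ± 0.17), Hapln2 (1.74 ± 0.26), the galactolipid enzymes Ugt8a (1.52 ± 0.16) and Fa2h (1.44 ± 0.20) and the myelin transcription factor Myrf (1.29 ± 0.18) rose with them. Anln, a cytokinesis protein also used as a myelin marker, changed by −1.55 ± 0.19. These values rest in part on the window. With 50 kb each side the myelin list lay 0.61 above matched lists, Mobp, Mag and Myrf rose by 1.31, 1.53 and 0.65, still called, and Hapln2 stood at −0.38 and was not called.

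Mitogen signalling and proliferation genes narrowed. Of 18 receptor tyrosine kinase and MAPK feedback genes, 10 were narrower and 0 wider (10 adjusted over the list alone), 0.79 below matched lists, a difference of −0.79 (adjusted p = 0.00052, matched random lists, lower in 2 of 2 lines). Besides Spry4 and Ccnd1 these were Etv5 (−1.79), Etv1 (−1.34), Etv4 (−1.34), Dusp6 (−0.91), Spry1 (−0.78), Spred1 (−0.77), Spred2 (−0.74) and Junb (−0.60). Myc and Fos stood at −0.48 and 0.27 and were not called. Of 16 cell cycle genes tested, 11 were narrower and 1 wider, the same counts as when adjusted over the list alone, with a difference of −0.62 from matched lists (adjusted p = 0.00052, matched random lists, lower in 2 of 2 lines). Cdk1, the mitotic kinase, changed by −2.06 ± 0.23, from 3.29 and 2.72 kb to 0 kb, Rrm2 by −1.72 ± 0.22 and Mki67, the Ki-67 antigen, by −1.48 ± 0.29. E2f1 widened by 0.87 ± 0.19. The OPC medium contained basic FGF and PDGFA, mitogens of these cells, per the labels' protocols.

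**Figure D3:**
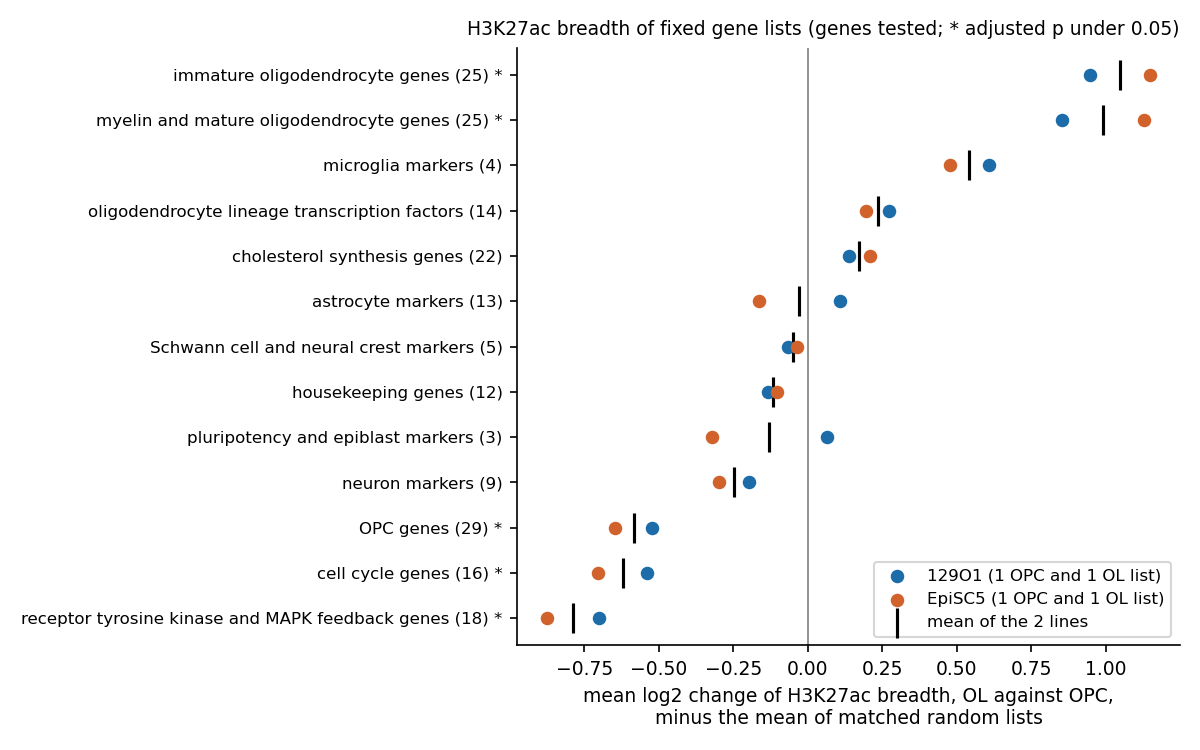
Mean log2 change of H3K27ac breadth for 13 gene lists, OL against OPC, after subtracting the mean of matched random lists, with 1 point per cell line and a bar for their mean. The 2 oligodendrocyte lists lie near 1.05 and 0.99, and the OPC, cell cycle and MAPK feedback lists at −0.58, −0.62 and −0.79.

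Lineage transcription factors did not move as a list (difference 0.24, adjusted p = 0.381, matched random lists), with 4 of 14 wider, 1 narrower and the same counts adjusted over the list alone. Their mean change was 0.19 and their median −0.07. The wider members were Zfp536 (1.99), St18 (1.46), Zeb2 (1.18) and Zfp488 (1.07), and Prrx1 was narrower (−1.34). Sox6 itself stood at −0.08 ± 0.10, Olig2 at −0.12 ± 0.16 and Sox10 at 0.07 ± 0.17, none of them called. Without scaling Sox6 and Olig2 were slightly above 0, at 0.07 and 0.01. Cholesterol synthesis genes differed by 0.17 (adjusted p = 0.343, matched random lists), with 3 wider, among them Hsd17b7 (1.25), and 1 narrower of 22, Fdps (−1.16), the same counts adjusted over the list alone, a mean of 0.02 and a median of −0.07.

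Markers of other cell types and the housekeeping list did not pass. Their differences were −0.03 for 13 astrocyte genes (1 wider, 2 narrower), −0.25 for 9 neuron genes (1 and 2), 0.54 for 4 microglia genes (1 and 0), −0.13 for 3 pluripotency genes (0 and 0), −0.05 for 5 Schwann cell and neural crest genes (1 and 2) and −0.12 for 12 housekeeping genes (0 and 3), with adjusted p from 0.188 to 0.902 against matched random lists. Adjusted over the list alone, the wider and narrower counts were 2 and 3 for astrocyte, 1 and 4 for neuron and unchanged for the remaining 4 lists. In the order above the full lists held 14, 16, 12, 14, 11 and 14 genes, and members not tested had a mean covered length under 1 kb. The microglia, pluripotency and Schwann cell lists, with 3 to 5 genes tested, are thus a weak check. Members called included S100b (1.03) and Fabp7 (−1.05) of the astrocyte list, Map2 (−1.58) and Elavl3 (1.31) of the neuron list, Csf1r (1.62) of the microglia list and Mitf (1.67) of the Schwann cell list. The microglia genes had a mean of 0.23 but a median of −0.18. Gfap and Aqp4, both astrocyte markers, stood at −0.03 and 0.14, not called.

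The third comparison asked where SOX6 was bound in OPC and how far both lines shared it. By the smaller of the 2 OPC lists, the longest SOX6-covered length was over its own gene Sox6 (chromosome 7, 115470872 to 116040776). It was 11.8 kb in 129O1 and 8.68 kb in EpiSC5. Tex14 (7.38 and 7.13 kb), Lsamp (10.5 and 6.86 kb), the related factor gene Sox5 (8.42 and 5.75 kb), Nrxn3 (7.17 and 5.70 kb), Opcml (7.70 and 5.67 kb), Ncald (10.3 and 5.55 kb), Tnr (7.22 and 4.92 kb), Maml2 (5.97 and 4.76 kb) and Myo10 (6.58 and 4.75 kb) followed. Of these 10 genes, H3K27ac narrowed in OL at Tex14, Sox5, Nrxn3, Ncald, Maml2 and Myo10 and widened at Lsamp, Opcml and Tnr. The ranking is not corrected for gene length and favours long genes. As a share of the gene body, SOX6 covered 2.06% and 1.52% of Sox6 in 129O1 and EpiSC5. Tex14 (4.90% and 4.73%) and Myo10 (3.44% and 2.49%) had more, as did Olig2 (7.83% and 7.80%), which is outside the 10. EpiSC5 peaks were found in 129O1 for 90.3% and 129O1 peaks in EpiSC5 for 60.8%, against 0.631% and 0.428% after circular shifts (p = 0.001 for each, permutation by circular shifts, the smallest that 1000 shifts can give). SOX6 lay near 26 of the 30 OPC genes and 23 of the 25 immature oligodendrocyte genes in EpiSC5, against 32.6% of all protein-coding genes, a share not matched for gene length. Other lists also lay above it, with 85.7% of lineage transcription factors, 83.3% of MAPK feedback, 68.8% of myelin, 64.3% of astrocyte, 56.3% of neuron and 42.9% of housekeeping genes. Of the 3893 peaks with the highest score in 129O1, 99.02% were found in the full EpiSC5 list, an alternative added after the data were seen.

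The fourth comparison asked what became of SOX6 in OL, in EpiSC5 alone. Of 15487 OPC peaks on the chromosomes used, 9.61% were also called in OL, against 0.100% after shifts (p = 0.001, permutation by circular shifts). Of the OL peaks, 38.5% lay on a peak of OPC of the same line and 53.6% on a peak of OPC of 129O1. Sox6 had 0.218 kb and Sox5 0.248 kb of SOX6 in OL, and Opcml, Ncald, Maml2 and Myo10 were at 0 kb. This describes 1 OL library, with a shorter list and no repeat, so no difference between the states was tested. With 3893 peaks taken from each list, 11.3% of OPC peaks were called in OL and 11.6% of OL peaks in OPC of EpiSC5 and 12.6% in OPC of 129O1. From the higher-scoring 50% of each list 5.99% of OPC peaks were called in OL and 24.0% of OL peaks in OPC of EpiSC5.

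A small set of genes carried long SOX6 stretches in OL, counted over the body plus 10 kb each side. Frmd4a, coding for a scaffold protein, held 48.3 kb in OL against 5.99 and 4.15 kb in OPC of 129O1 and EpiSC5. Qk, which encodes the RNA-binding protein quaking required for myelination, held 46.3 kb against 7.60 and 1.17 kb. Bcas1 (chromosome 2, 170343973 to 170427911) held 44.4 kb against 1.59 and 0.980 kb, so that peaks covered 42.7% of the gene body in OL and 1.17% in OPC of EpiSC5. Nfasc held 26.3 kb (2.06 and 0.696 kb in OPC) and Mbp 17.2 kb (0.639 and 0.959 kb). Rasgef1b (11 kb), Fkbp15 (9.19 kb), its neighbour Slc31a2 (8.52 kb), Chn2 (8.38 kb) and Fam13c (7.27 kb) completed the 10 largest. At Rasgef1b, Fkbp15 and Chn2 peaks covered 9.61%, 2.72% and 0.362% of the body, so that most of their SOX6 lay beside it. The 5 largest clusters of peaks in OL took 13.9% of all SOX6-covered length, against 0.679% and 0.351% in OPC of 129O1 and EpiSC5.

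**Figure D4:**
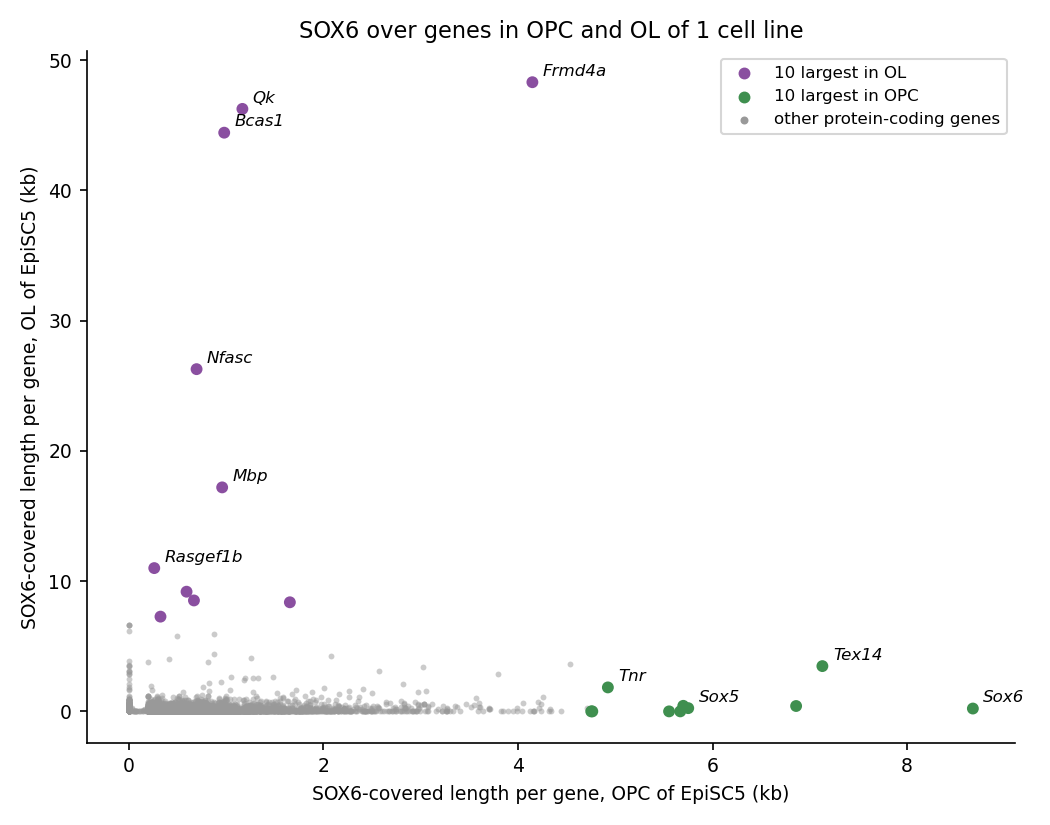
SOX6-covered length per protein-coding gene (body plus 10 kb each side, kb) in OPC (horizontal) and OL (vertical) of EpiSC5, 1 library each, 1 point per gene. Frmd4a, Qk and Bcas1 lie at 48.3, 46.3 and 44.4 kb in OL, while Sox6 lies at 8.68 kb in OPC and 0.218 kb in OL.

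Acetylation covered little of these stretches, Mbp apart. Over Bcas1 the 129O1 and EpiSC5 lists held 10.8 and 6.71 kb of H3K27ac in OPC and 11.7 and 11.6 kb in OL, and 9.93% of the OL SOX6 length lay within OL H3K27ac of the same line. The share was 12% at Frmd4a, 16.6% at Nfasc, 28.5% at Qk and 54.5% at Mbp. H3K27ac widened in OL at 7 of the 10 genes, while at Bcas1, Qk and Fam13c it was not called. Tnr, Fyn and Tns3, which had 114, 92.9 and 87.5 kb of H3K27ac in OL of EpiSC5, held 1.84, 2.06 and 2.85 kb of SOX6 there.

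**Figure D5:**
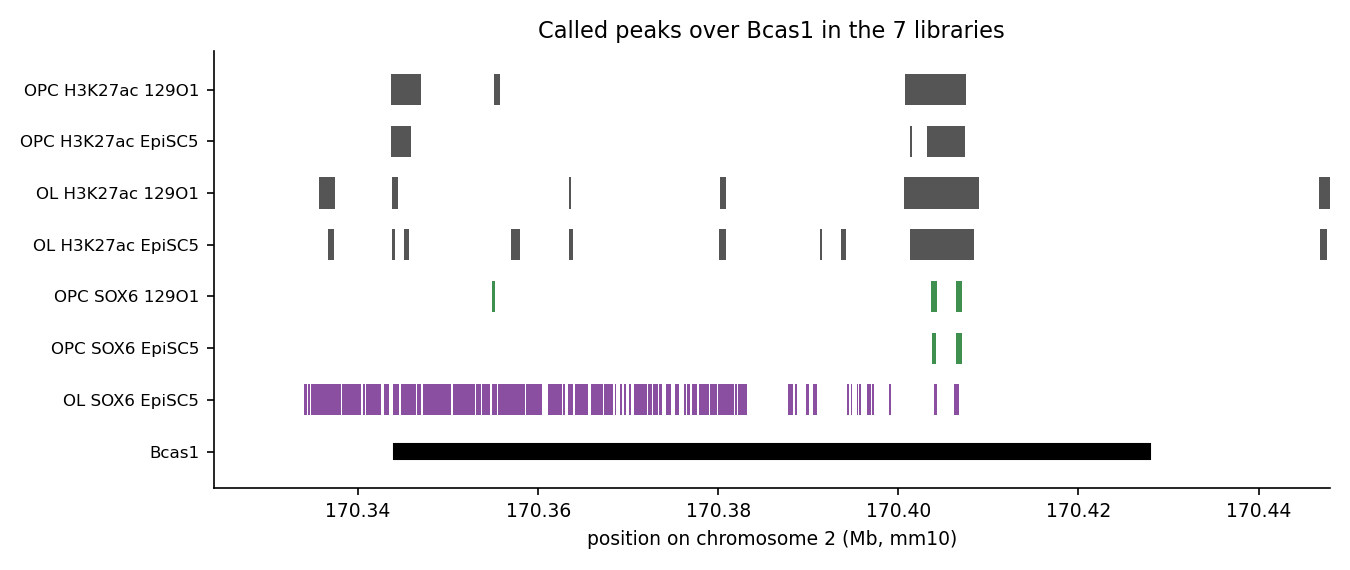
Called peaks of the 7 libraries over Bcas1 and 20 kb each side on chromosome 2 (position in Mb, mm10), with the gene as a black bar and its strand not shown. SOX6 in OL forms a run of 55 peaks that together cover 44.4 kb of a span of 72.7 kb, while OPC of EpiSC5 has 2 SOX6 peaks over the gene and 10 kb each side.

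The fifth comparison set SOX6 against H3K27ac of the same line. OPC SOX6 peaks lay in OPC H3K27ac for 69.4% in 129O1 and 68.0% in EpiSC5, and in OL H3K27ac for 60.9% and 55.7%. OL SOX6 peaks lay in OL H3K27ac for 74.1% and in OPC H3K27ac for 64.6%. Shifted lists gave between 1.86% and 2.52% (p = 0.001 for each, permutation by circular shifts). Of regions held by OPC lists alone, 39.9% and 31.9% carried an OPC SOX6 peak of 129O1 and EpiSC5 and 0.346% an OL SOX6 peak. Of regions held by OL lists alone, 14.8% and 8.88% carried an OPC SOX6 peak and 3.53% an OL SOX6 peak, while regions in all 4 lists carried SOX6 in 57.5%, 43.0% and 15.4%. EpiSC5 OPC peaks that were also called in OL lay in OL H3K27ac for 91.7%, and those not called in OL for 51.9%. The peaks also called in OL lay more often in OPC H3K27ac of EpiSC5 too, for 85.0% against 66.2%.

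Broad H3K27ac domains, made by joining peaks within 12.5 kb and ranked by covered length, numbered 1029 and 985 in OPC of 129O1 and EpiSC5 and 837 and 1032 in OL. Of the OPC domains, 74.2% of those of 129O1 and 77.8% of those of EpiSC5 were shared with the other line. Of the OL domains, 76.1% of those of 129O1 and 63.6% of those of EpiSC5 were. In OL of the same line 38.5% of the 129O1 and 35.9% of the EpiSC5 OPC domains were broad. OPC SOX6 peaks were present in 94.4% of broad and 49.8% of other OPC domains in 129O1, and in 85.3% and 38.6% in EpiSC5. OL SOX6 peaks were present in 43.6% of broad and 10.4% of other OL domains. Shifted lists gave 17.6% and 3.02% in OPC of 129O1, 11.3% and 1.86% in OPC of EpiSC5 and 3.67% and 0.540% in OL. All shares lay above these (p = 0.001 for each, permutation by circular shifts). The shifts spread peaks over whole chromosomes, so this shows only that SOX6 lay in acetylated domains more often than peaks placed without regard to them. Per 10 kb of domain the order turned, with 1.10 and 0.88 SOX6 peaks in broad OPC domains against 1.81 and 1.53 in other domains, so that longer OPC domains held SOX6 more often but not more densely. Without joining peaks the gap was smaller, 2.81 and 2.49 against 3.32 and 2.88, and in OL it was 0.276 against 0.309, or 0.301 against 0.299 with domains ranked by score. With equal numbers of SOX6 peaks the share of broad OPC domains was 47.1% in 129O1 and 45.0% in EpiSC5, and without joining peaks the share of broad OL domains was 28.8%.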

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

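Of the tests in this part, those on the SOX6 stretches in OL were chosen only after their results had been seen, while the tests on chromosomes 17 and X were written down first.

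Long SOX6 stretches over Frmd4a, Qk, Bcas1, Nfasc and Mbp rest on a single OL library of EpiSC5. Recovery of acetylated chromatin irrespective of SOX6 would place most of that length in H3K27ac, yet 16.7% of the SOX6 length in the 20 largest clusters lay within OL H3K27ac of the same line. A fixed property of the loci, such as extra copies or mapping background in EpiSC5, would show in OPC too, yet SOX6 peaks of OPC of EpiSC5 covered 1.60% of it. The clusters were picked as the longest in OL, which lowers that share in part. In OPC of 129O1 the cluster at Hes5 and Pank4 held 5.46 kb of SOX6, close to the 5.93 kb in OL of EpiSC5. At most clusters OPC of 129O1 held far less than OL, with 1.26 kb at Bcas1 and 0 kb at Mbp. A background that arises in OL alone was not tested and has no control here, because no input of OL is among the samples. Signal over strongly transcribed genes stays open, because transcription was not measured, although the longest SOX6-covered length among 45 housekeeping and other myelin genes was 1.17 kb, at Cnp. A change of SOX6 occupancy between OPC and OL may underlie the stretches, as a hypothesis that 1 library cannot settle.

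Chromosome 17 held 2.66 times as many OPC SOX6 peaks in 129O1 as in EpiSC5, against 1.48 over the genome. Chromosome 3 came next among the autosomes at 1.76, and of the 15 bins of 5 Mb with the largest excess 4 lay on it between 140000001 and 160000000, which extra copies of chromosome 17 would leave unexplained. The excess on chromosome 17 was spread, with 94.7% of its bins of 5 Mb above the genome-wide ratio. In H3K27ac the same chromosome had the highest line ratio of the 19 autosomes in OPC (1.19) and in OL (1.20), close to that of chromosome 3 in OPC (1.17) and of chromosome 11 in OL (1.16). Extra copies of chromosome 17 in the 129O1 cells are therefore a candidate explanation, while the 3 bins with the largest excess held 32.4% of it, which leaves room for a part from a few loci. The inputs, which could decide it, were not analysed here, and 129O1 and EpiSC5 also differ in strain, which was not tested.

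The X chromosome held fewer H3K27ac peaks in OL than in OPC in both lines (ratios 0.80 and 0.75), whereas the autosomes lay between 1.01 and 1.20. The Y chromosome also held fewer, 28 in OPC and 17 in OL of 129O1 and 13 and 9 in EpiSC5 (ratios 0.61 and 0.69). If weaker X peaks had only dropped under the threshold, X peaks would be kept like autosomal peaks of the same −log10 q and width. In 129O1 61.3% were kept in OL against 69.6% of matched peaks (middle 95% of draws 67.1 to 72.2), and in EpiSC5 52.8% against 59.5% (56.5 to 62.5), so this does not account for the whole difference. Of 346 X-linked genes tested, 28.9% were narrower and 4.05% wider, against 16.0% and 12.8% of autosomal genes. A difference in X copy number between the cultures and a change with the state both stay open and were not tested.

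Several results went opposite ways in the 2 lines, and these differences were not tested. H3K27ac breadth changed by −1.16 in 129O1 and 1.01 in EpiSC5 at Pkhd1, by 1.25 and −1.12 at Tagln3, and by −1.10 and 1.02 at Robo2. Relative to matched genes, astrocyte markers stood at 0.11 in 129O1 and −0.16 in EpiSC5, and pluripotency and epiblast markers at 0.0644 and −0.32.

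Peaks on unplaced contigs or the mitochondrial genome, which no comparison used, numbered 17 and 10 in OPC H3K27ac of 129O1 and EpiSC5, 70 and 55 in OL H3K27ac, 7 and 3 in OPC SOX6 and 56 in OL SOX6 of EpiSC5.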

How the results depend on the processing

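The alternatives named as gene body alone, lncRNA genes, and equal numbers of SOX6 peaks against a full list were chosen after seeing the data, the others before. All 70 alternative SOX6 shares stayed above their shifted lists and 60 alternative list differences kept their sign and side of the threshold. The other 5 passed in neither case: astrocyte markers ranged from −0.16 to 0.11 and pluripotency markers from −0.32 to 0.0644 between the lines, and with 50 kb windows pluripotency, Schwann cell and housekeeping lists stood at 0.402, 0.0010 and 0.0679. That window also lowered the myelin list from 0.99 to 0.61. The cause was not tested. Of the single genes, Hapln2 turned to −0.38 with 50 kb windows, and Sox6 and Olig2 to 0.0662 and 0.0142 without scaling and Sox6 to 0.00422 from the higher-scoring 50% of each list, all uncalled. Counts moved more. OPC and OL regions numbered 6032 and 6459 with equal numbers of peaks, 2476 and 4045 from the higher-scoring 50% of each list, and 9814 to 11201 and 12608 to 14547 with either replicate left out, where 1 line no longer has to repeat the other. Wider and narrower genes numbered 129 and 43 from the higher-scoring 50% (27 of the named genes lost their call), 2383 and 3659 with 50 kb windows, and 636 and 468 for a change of at least 1 in both lines with no model. Narrower genes numbered 1207 with a 3 kb filter, 1143 without scaling, 1230 with equal numbers of peaks and 1014 over the gene body alone. With no filter limma called 0 of 21887 genes wider and 0 narrower (4814 at an unadjusted p under 0.05), and 49 named genes lost their call with the same changes. At a change of at least 1 each line alone, with no test, gave 802 to 1018 wider and 668 to 1612 narrower genes. Without the replicate block 1234 were wider and 1368 narrower, and Sox11 and Luzp2 were among the named genes to lose their call, with the same changes. Promoter windows, start-site removal and the SOX motif alternatives were not run, for want of strand and sequence. With the cell line in the model, fits without 1 library leave no residual degree of freedom. Such fits without the cell line were not run. Unknown depth limits every presence comparison.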

Other observations

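The tests on genes with long SOX6 stretches in OL, the one with 1 gene for each stretch included, were chosen only after the result was seen, and those on SOX6 in OPC and on Hox genes were written before. The microRNA and Hox loci were singled out after their values were seen.

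The cell lines differed in H3K27ac at 11 genes regardless of state (limma, adjusted p under 0.05), and all 9 that were wider in 129O1 were Hox genes, the regulators of position along the body axis. Hoxa7 (chromosome 6, 52215623 to 52218573) had 21.7 kb in OPC and 12.8 kb in OL of 129O1 and 0 kb in both EpiSC5 lists. The others were Hoxa5, Hoxa6, Hoxa9, Hoxb6, Hoxb7, Hoxb8, Hoxd3 and Hoxd8. They lie in 3 clusters where their windows overlap and share peaks, so the 9 calls are not independent. Rbfox1 and Gpr37 were wider in EpiSC5. Of all 39 Hox genes, 16 had H3K27ac in their body in both 129O1 lists and 7 in both EpiSC5 lists (8 in any EpiSC5 list), the 129O1 lists also being the longer ones. That the lines hold different Hox codes stays open. Of the other 9 Hox genes with H3K27ac in their body, 3 (33.3%) had more in 129O1 in both states, but this share leaves out the called genes, and Hoxa2, covered over its full 2.42 kb in all 4 lists, could not show a gain, so it decides nothing.

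H3K27ac at microRNA loci took several courses. Mir219a-2 (chromosome 2, 29845631 to 29845727), a microRNA that promotes oligodendrocyte differentiation, had 0.721 and 0.701 kb of H3K27ac within 10 kb in OPC of 129O1 and EpiSC5, and 16.3 and 14.0 kb in OL. Mir338 went from 2.03 and 1.35 kb to 6.94 and 4.76 kb. Mir219a-1, the other copy, stood at 7.63 and 6.51 kb in OPC and 8.16 and 5.36 kb in OL. Mir9-1 had its whole window of 20.1 kb covered in both OPC lists, the most that could be counted, and 19 and 12.8 kb in OL, with 3.69 and 2.99 kb of SOX6 in OPC and 0 kb in OL. These loci were not tested.

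SOX6 in OPC was set against later H3K27ac change, using uncalled genes matched on OPC coverage and length. Genes that widened had a mean of 2.01 SOX6 peaks in OPC of 129O1 and 1.35 in EpiSC5. Matched genes had 1.67 and 1.07 (one-sided p = 0.0001 for each, permutation over 10000 random lists, the smallest they can give). Genes that narrowed had 1.98 in 129O1 and 1.35 in EpiSC5, against 2.09 and 1.33. In 129O1 this argues against more SOX6 at narrowing genes, the value being higher than in 0.08% of random lists (one-sided p = 0.9992, permutation over random lists). In EpiSC5 the matter stays undecided (one-sided p = 0.161, permutation over random lists). SOX6 in OPC may mark genes that later gain acetylation, a hypothesis from peak lists that says nothing of mechanism. Among single regions, 39.9% and 31.9% of those held by OPC lists alone carried OPC SOX6 of 129O1 and EpiSC5. Regions in all 4 lists carried it in 57.5% and 43.0%, but were wider (median 2106 against 1144 bp). Regions held by OL lists alone carried it in 14.8% and 8.88%. They lack OPC H3K27ac by definition, where most OPC SOX6 peaks lay, so their low share cannot bear on the question. Genes that gained and genes that lost were not compared with each other.

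Genes with at least 5 kb of SOX6 in OL may also gain H3K27ac more often. Of 16 such genes 68.8% were wider, against 27.6% of matched genes (one-sided p = 0.0003, permutation over random lists). Neighbours share stretches, and with 1 gene for each stretch 7 of 11 were wider, or 63.6% against 33.4% (one-sided p = 0.0351, permutation over random lists). Bcas1, Qk and Fam13c are among those not called.

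A stretch of 122 kb at the end of the Y chromosome, from 90717548 to 90839995, held 28.1 kb of SOX6 and 53.7 kb of H3K27ac in OPC of 129O1, against 0.443 and 0.781 kb in OPC of EpiSC5. In OL it held 11.9 kb of H3K27ac in 129O1 and 0.299 kb in EpiSC5. On the X chromosome, a stretch over Mid1 from 169975854 to 170022439 held 5.07 kb of SOX6 and 17.8 kb of H3K27ac in OPC of 129O1. OPC of EpiSC5 had 0 and 0.794 kb there. Whether the X and Y stretches share sequence was not examined, so they cannot be counted as separate loci. The cause was not tested.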
